A study of Arabidopsis thaliana with 4 samples.

How the data were processed

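Small RNA libraries were made from total RNA of 2-week-old seedlings with an Illumina TruSeq small RNA kit, per the labels' protocols. The 4 libraries fell into 2 groups of 2, WT and urt1, by the genotype in the labels. Nothing in the labels says that the replicates came from separate cultures, so the p values measure only the spread between these libraries, which may be technical. Replicate libraries differed by far more than sampling noise, with a chi-square over degrees of freedom from 139 to 5008 across miRNA or siRNA names, and each was kept as 1 sample.

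Each library had a deposited table of miRNA isoforms and one of siRNA isoforms, with the canonical sequence, the read sequence, the tail and a read number. The deposited values were treated as estimated counts. Per the file headers they are normalized numbers of reads, and the values themselves are whole numbers or fractions, as when a read is divided among the names or places it matches, with totals that differ between libraries. They were rounded to whole numbers before any count test. The submitters' processing notes name CASAVA 1.8.2, Bowtie, bedtools 2.17.5 and the genome build TAIR10. Their roles and settings, and the version of Bowtie, are not given in the sources used here. In 1 of the 8 tables the headers of tail length and tail composition were exchanged, as the values showed, and the columns were read by content. All tails in the tables are runs of 1 base, so a class of mixed tails was not formed, and a tail that holds a U equals a tail made of U. Names with identical mature sequences (116 names share a sequence) divide their reads, so values of such family members are uncertain and not independent.

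For each miRNA or siRNA, tailed reads were tested against all other reads with edgeR 4.0.16 in R 4.3.3. The layout had 2 columns per library, a term for each library, a term for tailed reads and the genotype by tailed term that was tested (glmQLFit and glmQLFTest), so that library size cancels. Names needed at least 10 reads in every library and 10 tailed reads over all 4, which left 132 miRNA names (102 sequences) for tailing, 121 for uridylation and 8 siRNAs. Abundance was tested with edgeR's quasi-likelihood test, TMM scaling and filterByExpr, on 185 miRNA names and 8 siRNAs. Adjusted p values are Benjamini-Hochberg values with a threshold of 0.05. Shares of reads per library were compared by exact two-sided permutation tests. The Wilson 95% interval of a library's tailed or trimmed share reached at most 0.0596 percentage points to either side. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

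Lists fixed before the data were examined were tested with camera and fry from limma 3.58.1: conserved and less conserved families, reported nucleotidyl transferase substrates, nutrient-responsive families, regulators of developmental transcription factors, silencing pathway miRNAs and phased siRNA triggers, age-linked families, and groups by mature length and first base. Adjustment was over the 45 tests of lists in the fits of tailing, uridylation and abundance. Lists of guide and star strands and of siRNAs by TAS family were not formed, since the names do not mark them, and siRNA length classes had too few members. Named miRNAs followed a rule fixed at the same time: the 10 with most reads per name, the 10 with the highest mean tailed share in WT, and all tested members of the miR158, miR165, miR166 and miR171 families, with identical sequences counted once. For siRNAs 5 took the place of 10. Up to 10 miRNAs past the threshold in each direction would also have been named.

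Mature sequences and whole tailed reads were matched exactly to the TAIR10.1 reference, and all coordinates are 1-based positions from that match. A tailed read counted as matching wherever in the genome it matched, on either strand, also away from the miRNA's own locus. No coordinates of the submitters were used. The canonical siR-5 sequence had no exact match there, and siR-7 matched 2 intergenic places. Alternatives were other count filters, a replicate block, limma on log2 odds with 0.5 added to each count, a beta-binomial test, no abundance trend, merged identical sequences, tails of 1 nt or of 2 nt or more, full-length ends only, U tails against untailed reads, DESeq2 1.42.0, other scalings, untailed full-length reads, equal weights, the most abundant name left out, and each library left out in turn. Counting tailed reads that match the genome as untailed, and fry under other scalings, were added after the data were seen.

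The tests were run first on data simulated from the real totals, with 20 simulations per step. For tailing of the 132 miRNA names, edgeR called 54.8% of 2-fold and 84.5% of 4-fold changes in the odds and 1.41% of unchanged names. For abundance of the 185 names it called 16.8% of 2-fold and 76.5% of 4-fold changes and 0.621% of unchanged names. All simulated names shared the same spread between libraries, an extra log2 SD of 0.198 for tailing, so recovery is lower for miRNAs that vary more. Over the 20 simulations of tailing, 400 names were changed by each factor and 1840 were not, and so many changes ease the adjustment. In the real tailing fit the unadjusted confidence interval reached a median of 0.91 to either side, where a 2-fold change is 1 on the log2 scale. The simulated recovery may thus be too high even for a typical name. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.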

Results

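Small RNA was sequenced from 2-week-old whole seedlings of Arabidopsis thaliana ecotype Col-0, in 2 wild-type (WT) libraries and 2 libraries of the urt1 mutant. URT1 is a uridylyltransferase, an enzyme that adds uridines to the 3' ends of RNA. The study asked how miRNAs and siRNAs are tailed, that is, extended at the 3' end, in WT and urt1. For each library the tables listed the isoforms of known miRNAs and of 8 siRNAs with their 3' trimming, tail and read count. The miRNA tables held 1881054 reads in WT replicate 1, 1624789 reads in WT replicate 2, 2137528 reads in urt1 replicate 1 and 2682428 reads in urt1 replicate 2. The siRNA tables held 309494, 424370, 670701 and 696986 reads in the same order. In all, 343 miRNA names with 269 different sequences were listed, and 243 names had reads in all 4 libraries. The URT1 transcript was not analysed here, since small RNA tables do not measure it, and so the genotype labels were not checked from the data.

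Over all reads, tails on miRNAs were mostly uridines in both genotypes, and this rested largely on 1 abundant miRNA, miR158a-3p. A U tail was on 5.89% ± 0.279 of miRNA reads in WT and on 7.52% ± 3.63 in urt1 (SD, n = 2 each). C tails were on 1.75% ± 0.271 and 2.38% ± 0.695, A tails on 0.146% ± 0.00181 and 0.158% ± 0.0273, and G tails on 0.109% ± 0.0214 and 0.0868% ± 0.0185, in WT and urt1 in that order (SD, n = 2 each). U made up 73.3% and 76.0% of the tailed reads in the WT libraries, and 70.2% and 76.2% in the urt1 libraries. Between 66.2% and 77.0% of all U-tailed reads in each library came from miR158a-3p. With that name left out, U tails were on 1.97% ± 0.447 of reads in WT and 2.41% ± 0.770 in urt1 and C tails on 1.77% ± 0.297 and 2.48% ± 0.923, of 3.97% and 5.11% tailed (SD, n = 2 each). With equal weight for each miRNA with at least 10 reads in every library, U tails were on 9.82% ± 1.02 and 10.2% ± 0.786 and C tails on 6.16% ± 0.365 and 6.48% ± 0.250, of 19.5% and 19.8% tailed (SD, n = 2 each). Tails of 1 nt were on 5.92% ± 0.237 of reads in WT and 7.65% ± 2.68 in urt1, tails of 2 nt on 1.07% ± 0.218 and 1.41% ± 0.987, and tails of 3 nt or more on 0.901% ± 0.118 and 1.08% ± 0.711 (SD, n = 2 each).

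The share of miRNA reads with any tail was 7.89% ± 0.573 in WT and 10.1% ± 4.37 in urt1 (SD, n = 2 each), a difference smaller than the spread between the urt1 replicates. The libraries stood at 8.30% and 7.49% in WT and at 7.05% and 13.2% in urt1. The difference of 2.25 percentage points had an exact two-sided permutation p = 1, where the smallest p that 2 libraries against 2 can give is 0.333. Its direction rested on urt1 replicate 2: without that library the difference was -0.840 percentage points, and without urt1 replicate 1 it was 5.35. With miR158a-3p left out, the tailed share was 3.97% ± 0.769 in WT and 5.11% ± 1.74 in urt1 (SD, n = 2 each). When each miRNA with at least 10 reads in every library had equal weight, the mean tailed share was 19.5% ± 1.38 in WT and 19.8% ± 0.386 in urt1 (SD, n = 2 each).

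**Figure D1:**
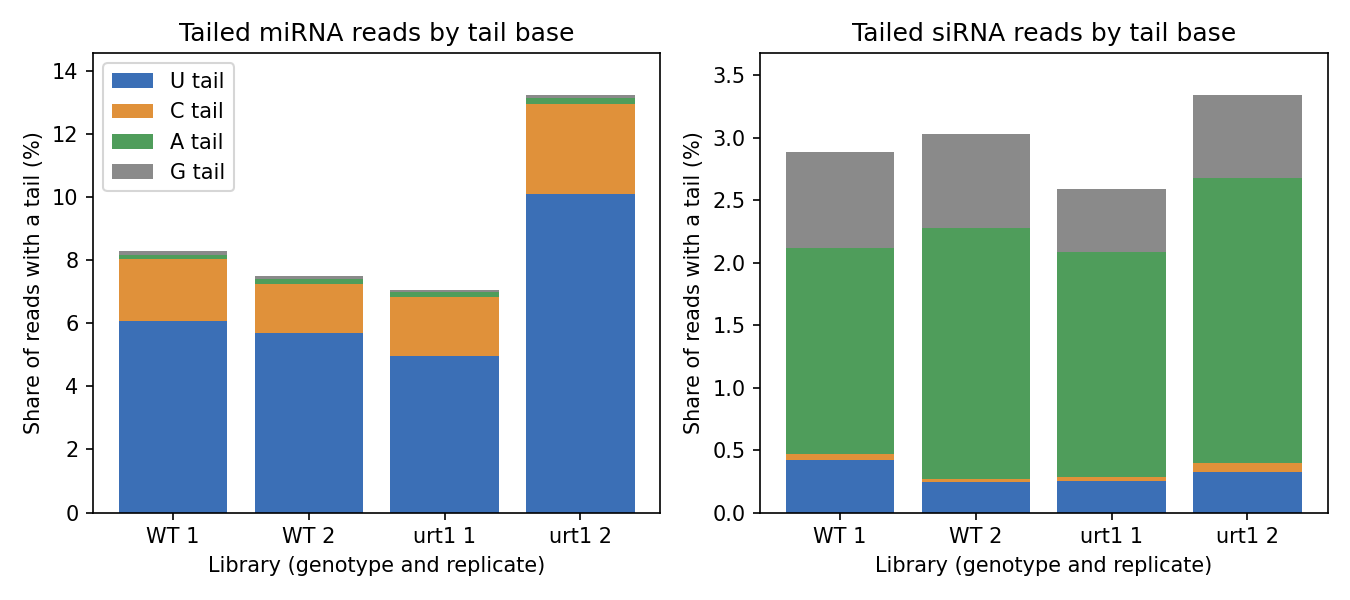
Stacked bars give the share of miRNA reads (left) and siRNA reads (right) with a U, C, A or G tail, in percent, in each of the 4 libraries. U tails lead among miRNAs, A tails lead among siRNAs, and urt1 replicate 2 has the highest tailed miRNA share, 13.2%.

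Single miRNAs had very different tailed shares in both genotypes. The name with the most reads, miR158a-3p (chromosome 3, 3366349 to 3366368, minus strand, exon of AT3G10745), had a tail on 37.0% ± 6.39 of its reads in WT and 33.3% ± 7.34 in urt1 (SD, n = 2 each). Low shares were found for miR166a-3p (chromosome 2, 19176241 to 19176261, plus strand, exon of AT2G46685, 1 of 7 loci with this sequence) and miR165a-3p (chromosome 1, 78932 to 78952, minus strand, exon of AT1G01183, 1 of 2 loci), which target HD-ZIP III transcription factors. They were tailed on 0.238% ± 0.0221 in WT and 0.273% ± 0.0404 in urt1, and on 0.752% ± 0.0607 in WT and 0.747% ± 0.00231 in urt1, respectively (SD, n = 2 each). In WT and urt1, miR161.1 stood at 4.41% ± 0.316 and 3.94% ± 1.13, miR403-3p, a regulator of AGO2, at 13.6% ± 0.549 and 14.9% ± 2.52, and miR156d-5p and miR157c-5p, regulators of SPL transcription factors, at 28.7% ± 3.57 and 30.2% ± 2.29 and at 48.3% ± 4.75 and 49.3% ± 1.01 (SD, n = 2 each). The miR159 members miR159a and miR159b-3p, regulators of GAMYB-like genes, were tailed on 0.505% ± 0.0516 and 0.607% ± 0.0321 and on 3.53% ± 0.0591 and 3.98% ± 0.0554 (SD, n = 2 each). The lowest share among the 10 names with most reads (identical sequences counted once) was that of miR398b-3p, a regulator of copper superoxide dismutases, at 0.169% ± 0.0201 in WT and 0.159% ± 0.0175 in urt1 (SD, n = 2 each). Part of these tails may be genome sequence: over all libraries 77.3% of the tailed reads of miR403-3p, 64.5% for miR166a-3p, 43.9% for miR161.1, 43.0% for miR159b-3p, 41.5% for miR157c-5p and 35.8% for miR165a-3p matched the TAIR10.1 genome over the whole read. The share was 15.5% for miR398b-3p, 9.12% for miR159a, 3.15% for miR156d-5p and 0.558% for miR158a-3p.

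No miRNA passed the test for a change in its tailed share. Of 132 miRNA names, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.976. The beta-binomial and limma tests also called 0, with 8 and 6 unadjusted p values under 0.05. For miR158a-3p the log2 odds ratio of urt1 over WT was -0.24 (95% CI -0.63 to 0.15), and for the 10 names with most reads (identical sequences counted once) the estimates lay between -0.24 and 0.27. The estimate was above 0 for 74 names and below 0 for 58. The names with the lowest unadjusted p were miR865-5p, miR5026 and miR863-5p, the first 2 of them picked out after their values were seen. The rule named miR863-5p for its high tailed share in WT, a value that also enters its odds ratio. Names chosen in this way tend to be lower in urt1 even without an effect of genotype, and 7 of the 10 were lower. The 95% confidence interval reached a median of 0.91 on the log2 odds scale to either side, so smaller changes were not excluded for a typical name.

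**Figure D2:**
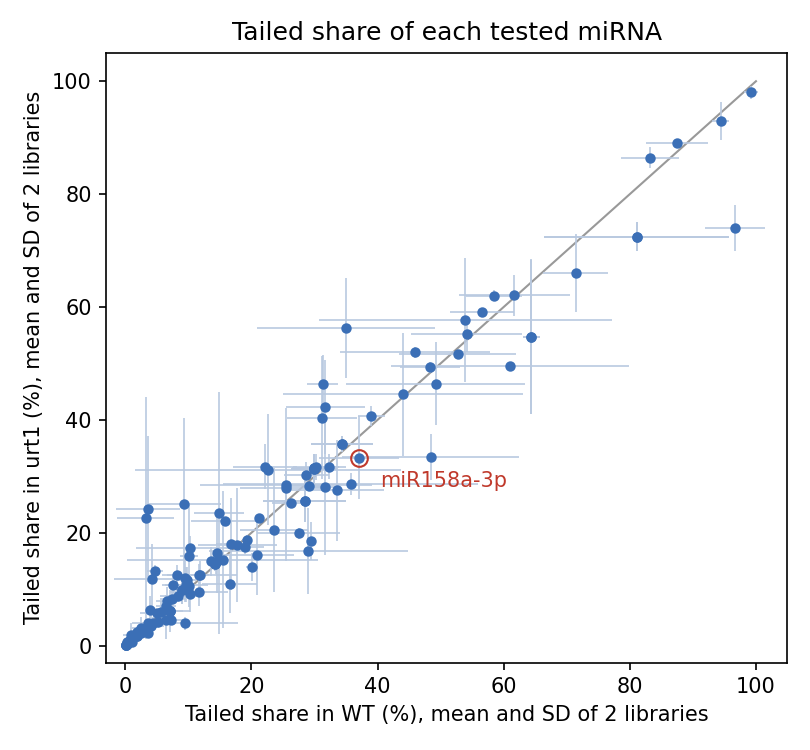
Each point is 1 of the 132 tested miRNA names, placed by its mean tailed share in WT (x axis, percent) and in urt1 (y axis, percent), with bars for the SD of 2 libraries. Points spread along the line of equal shares over nearly the whole range, and miR158a-3p lies at 37.0% in WT and 33.3% in urt1.

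The miR158, miR165, miR166 and miR171 families, which were named in advance as reported substrates of nucleotidyl transferases, were examined member by member. Of 10 measured members, 7 had an estimate above 0 and 3 below, and 0 passed the edgeR test. A close relative of miR158a-3p, miR158b (chromosome 1, 20772273 to 20772292, plus strand, exon of AT1G55591), was tailed on 33.5% ± 7.47 of reads in WT and 27.5% ± 8.88 in urt1 (SD, n = 2 each), with a log2 odds ratio of -0.42 (95% CI -1.16 to 0.33). From the other arm of the miR158a precursor, miR158a-5p stood at 11.7% ± 5.90 in WT and 12.6% ± 1.94 in urt1, and miR171a-3p, which targets GRAS-domain transcription factors, at 2.02% ± 1.44 and 2.47% ± 0.154 (SD, n = 2 each). The highest estimate in these families was that of miR166e-5p, 1.59 (95% CI -0.31 to 3.50), on 235 reads over all libraries.

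Among the miRNAs with the highest tailed share in WT, many tailed reads matched the genome over the whole read. The leading name was miR773a, with 99.2% ± 1.14 of reads tailed in WT and 98.0% ± 1.07 in urt1, followed by miR863-5p at 96.7% ± 4.71 and 74.0% ± 4.08 and miR841a-3p at 94.4% ± 1.36 and 93.0% ± 3.42 (SD, n = 2 each). Over all libraries 98.9%, 96.3% and 99.8% of their tailed reads matched the TAIR10.1 genome over the whole read. In 6 of the 10 names at least 90% of tailed reads matched in this way. The exceptions included miR393a-5p, a regulator of auxin receptors with the same sequence as miR393b-5p, at 81.1% ± 14.6 in WT and 72.5% ± 2.59 in urt1, and miR157c-3p at 58.5% ± 4.43 and 62.0% ± 0.943 (SD, n = 2 each). Of the tailed reads of these, 0% and 2.70% matched the genome. With matching reads counted as untailed, an alternative chosen after the data were seen, edgeR called 0 of 123 names, with 2 unadjusted p values under 0.05.

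**Figure D3:**
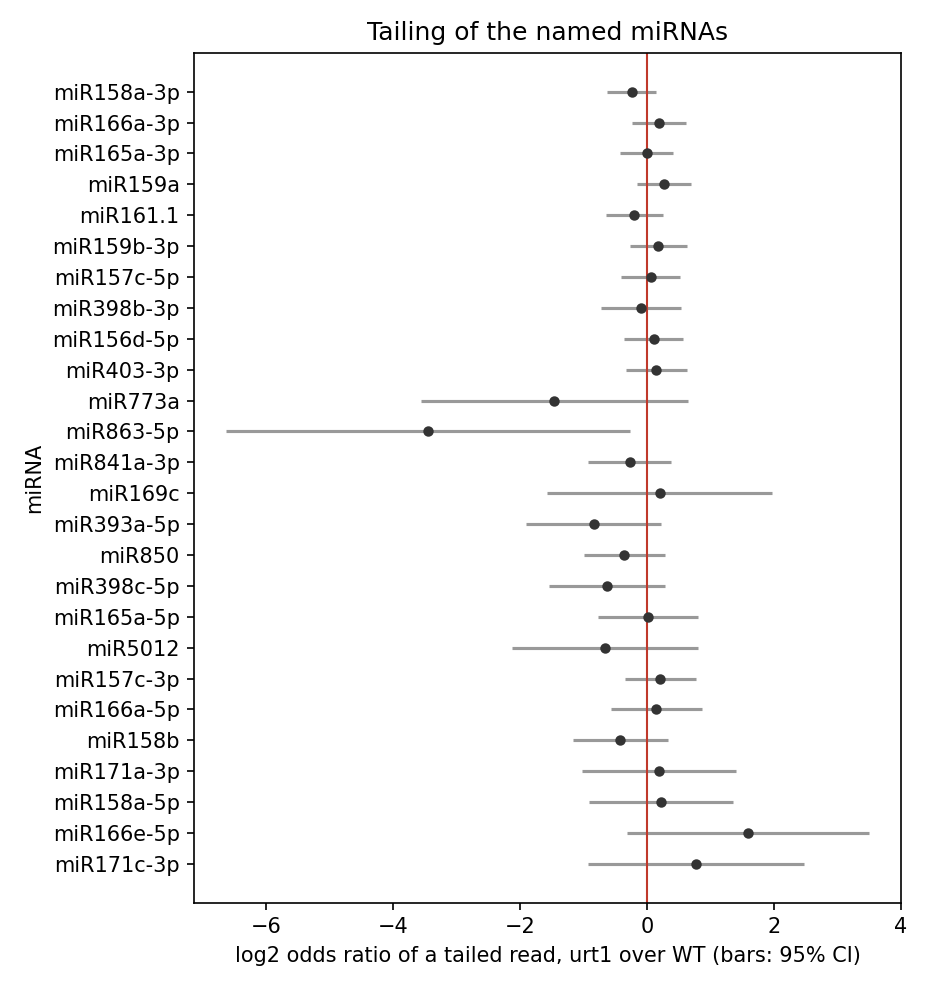
Points give the log2 odds ratio of a tailed read, urt1 over WT, for the 26 named miRNAs, with bars for the 95% confidence interval and a line at 0. The interval of miR863-5p excludes 0 before adjustment over the 132 names, and after adjustment no named miRNA passed. That miRNA was named for its high tailed share in WT, which also enters its odds ratio.

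Uridylation, the activity of URT1, was tested on its own. U tails were on 35.0% ± 6.29 of miR158a-3p reads in WT and 30.9% ± 7.63 in urt1 (SD, n = 2 each), a log2 odds ratio of -0.28 (95% CI -0.87 to 0.31). In WT and urt1 the U-tailed shares were 31.9% ± 7.74 and 25.4% ± 8.03 for miR158b, 20.6% ± 2.27 and 20.8% ± 1.02 for miR156d-5p, 21.6% ± 1.25 and 21.5% ± 0.150 for miR157c-5p and 12.6% ± 0.525 and 13.7% ± 2.81 for miR403-3p (SD, n = 2 each). Of these U-tailed reads, 82.9% for miR403-3p and 94.8% for miR157c-5p matched the genome over the whole read, so for both names the share does not tell added uridines from genome sequence, while 0% matched for miR158a-3p, miR158b and miR156d-5p. Among 121 names tested by edgeR, 0 passed, 1 had an unadjusted p under 0.05 (miR396b-5p, named after its value was seen), and 65 estimates were above 0 and 56 below. The beta-binomial and limma tests also called 0, each with 10 unadjusted p values under 0.05. With matching reads counted as untailed, an alternative chosen after the data were seen, edgeR called 0 of 111 names. Without urt1 replicate 2 the log2 odds ratio of miR158a-3p was -0.65, a value that rests on 1 urt1 library. By library its U-tailed share was 39.5% and 30.6% in WT and 25.5% and 36.3% in urt1. Replicate 2 of urt1 thus lay between the WT libraries.

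Trimmed 3' ends were also planned as a stand-in for RNA quality, a link that was not tested. They were found on 6.82% ± 0.0327 of miRNA reads in WT and 7.78% ± 2.52 in urt1 (SD, n = 2 each), with an exact two-sided permutation p = 1. The WT libraries stood at 6.84% and 6.80%, and the highest share was 9.56% in urt1 replicate 2. The difference of 0.963 percentage points turned to -0.817 without urt1 replicate 2, became 2.74 without urt1 replicate 1, and was -0.220 with miR158a-3p left out and -0.00315 with equal weights. On miR158a-3p, tails were more frequent on trimmed ends in every library. Full-length ends of miR158a-3p carried a tail on 20.7% and 23.3% of reads in the WT libraries and on 23.3% and 21.3% in the urt1 libraries. Of its ends trimmed by 1 nt, 81.1% (Wilson 95% CI 80.8 to 81.4) and 54.0% were tailed in the WT libraries, and 38.0% (Wilson 95% CI 37.6 to 38.3) and 76.3% in the urt1 libraries. The replicates of each genotype thus lay farther apart than the genotype means.

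**Figure D4:**
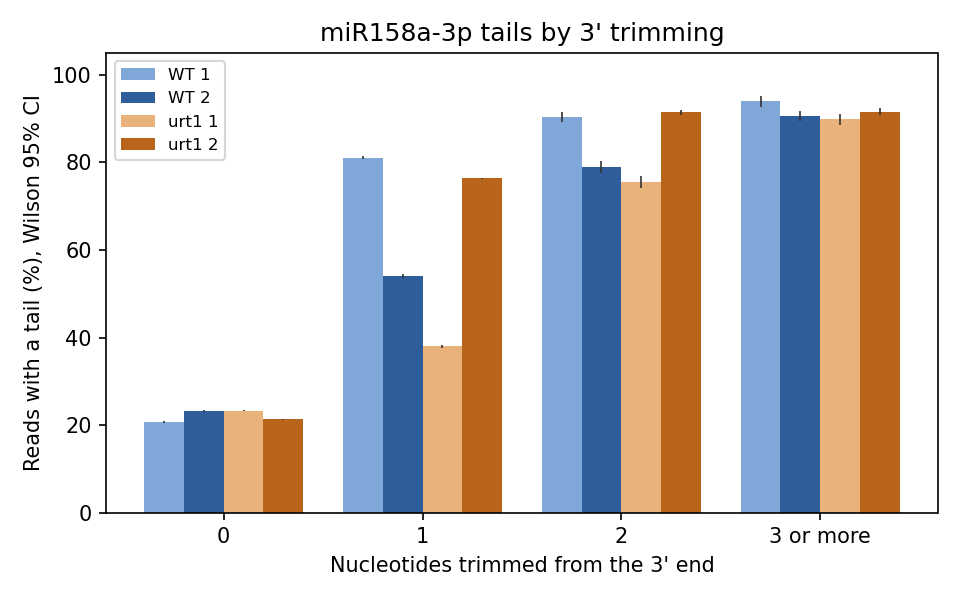
Bars give the share of miR158a-3p reads with a tail, in percent, by the number of nucleotides trimmed from the 3' end, for each of the 4 libraries, with Wilson 95% confidence intervals for counting error. Full-length ends lie between 20.7% and 23.3% in all libraries, whereas ends trimmed by 1 nt range from 38.0% to 81.1%.

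The tailing of siRNAs was the other question of the design. A tail was present on 2.96% ± 0.0984 of siRNA reads in WT and 2.97% ± 0.535 in urt1 (SD, n = 2 each), with an exact two-sided permutation p = 1. Over reads A was the commonest tail base, unlike on miRNAs, on 1.83% ± 0.254 of siRNA reads in WT and 2.04% ± 0.335 in urt1 (SD, n = 2 each). Most of these reads belonged to siR-8, which held 79.8% to 93.6% of siRNA reads and had an A tail on 2.19% and a U tail on 0.0480% of its reads over all libraries. The order turned without siR-8, with U tails on 2.51% ± 0.888 and 2.53% ± 0.0741 and A tails on 0.135% ± 0.0212 and 0.235% ± 0.129 in WT and urt1 (SD, n = 2 each). It also turned with equal weight for each siRNA, with U tails on 8.82% ± 1.12 and 8.48% ± 0.182 and A tails on 0.742% ± 0.122 and 0.639% ± 0.0224 (SD, n = 2 each). The difference in tailed share was 0.00726 percentage points over reads, -0.386 with equal weight for each siRNA, -0.0623 without WT replicate 1, 0.0768 without WT replicate 2, 0.385 without urt1 replicate 1 and -0.371 without urt1 replicate 2.

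The most tailed siRNAs were siR-1, siR-2 and siR-3. The siR-2 sequence (chromosome 2, 11722048 to 11722071, plus strand, antisense to AT2G27400, the TAS1A locus of trans-acting siRNAs) was tailed on 25.1% ± 0.503 of reads in WT and 24.1% ± 2.55 in urt1, siR-3 (chromosome 1, 24884383 to 24884403, plus strand, exon of AT1G66725, the miR163 precursor gene) on 22.2% ± 2.21 and 18.2% ± 0.203, and siR-1 (chromosome 5, 26949833 to 26949854, plus strand, exon of AT5G09935) on 19.3% ± 4.16 and 21.4% ± 5.50 (SD, n = 2 each). Their tails were mostly U, on 20.8%, 18.0% and 18.4% of reads over all libraries. In WT and urt1, siR-6 was tailed on 6.46% ± 1.95 and 4.69% ± 0.830, siR-5 on 4.09% ± 0.270 and 5.14% ± 0.162, siR-4 on 2.89% ± 1.69 and 3.03% ± 0.534, siR-7 on 1.29% ± 0.315 and 1.71% ± 0.466 and siR-8 on 3.00% ± 0.0214 and 2.93% ± 0.559 (SD, n = 2 each). The edgeR test called 0 of 8, with 0 unadjusted p values under 0.05 and a smallest adjusted p of 0.582, and limma and the beta-binomial test also called 0, with 0 and 1 such p values. Leaving out 1 library gave opposite calls for siR-8, with a log2 odds ratio of 0.15 without urt1 replicate 1 and -0.25 without urt1 replicate 2.

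The abundance of miRNAs was compared as background to their tailing, in reads scaled to the total of each miRNA table (RPM). The names with most reads included miR158a-3p, at 120807 ± 26464 RPM in WT and 172548 ± 59019 in urt1, and in WT and urt1 miR166a-3p stood at 78170.3 ± 2661 and 74769.5 ± 10218, miR165a-3p at 64129 ± 2699.9 and 58362 ± 8214 and miR159a at 63296 ± 3033 and 40752 ± 3216 (SD, n = 2 each). These values are per name. The miR166a-3p sequence is shared by 7 names and that of miR165a-3p by 2, which divide its reads. Both sequences thus hold more reads than shown, and ranks by sequence may differ. The log2 fold of urt1 over WT was 0.53 (95% CI -0.33 to 1.40) for miR158a-3p and -0.55 (95% CI -1.44 to 0.34) for miR159a. No miRNA passed the test. By edgeR 0 of 185 names were called, with 2 unadjusted p values under 0.05 (miR829-3p.1 and miR862-5p, named after their values were seen), and DESeq2 called 0 with 5. Without urt1 replicate 1 the count was 6, with miR158a-3p, miR447a.2-3p, miR5651, miR845a and miR863-3p called as higher and miR399a as lower in urt1. With no filter on low counts 1 name, miR845a, was called as higher.

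Families were also tested as lists. The nutrient-responsive list, which includes the copper-linked miR397, miR398 and miR408 and the phosphate-linked miR399 and miR827, had a median log2 fold in abundance of -0.40. Of its measured members 3 of 17 names, from 12 different sequences, lay above 0, and 0 passed, over all names tested or adjusted over the list alone. For miR398b-3p the values were 11044 ± 1269 RPM in WT and 7583 ± 1020.4 in urt1, and for miR398c-5p 109 ± 21.6 and 81.0 ± 23.6 (SD, n = 2 each). Of the age-linked list only miR156 and miR157 members had enough reads to be tested. It had a median of 0.24, with 19 of 21 names, from only 13 different sequences, above 0 and 0 passing, over all names or adjusted over the list alone. Here miR156d-5p stood at 7927 ± 2299.8 RPM in WT and 8562 ± 1979 in urt1 and miR157c-3p at 1551 ± 571 and 2145 ± 161 (SD, n = 2 each). By camera with a preset correlation of 0.01 the adjusted p was 7.7e-04 for the nutrient-responsive and 5.1e-04 for the age-linked list. With an estimated correlation the adjusted p was 0.995 for both. By fry it was 0.971 for both. Each list kept its direction under all 3 scalings, but this is no added support, since a scaling shifts all names nearly alike and camera compares a list with the other names. The nutrient-responsive call ended without WT replicate 1 (median -0.08) and its direction turned without urt1 replicate 2 (median 0.21), and the age-linked call ended without WT replicate 2 (median 0.10) and without urt1 replicate 1 (median 0.32).

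For tailing, the regulators of developmental transcription factors had a median log2 odds ratio of 0.10, with 47 of 61 names above 0, from 39 different sequences. Examples were miR159a at 0.27, miR166a-3p at 0.19 and miR156d-5p at 0.11. The camera adjusted p was 0.00476, and the adjusted p was 0.995 with an estimated correlation. The call ended without WT replicate 2 (median 0.02) and without urt1 replicate 1 (median 0.21), and the median was 0.27 without WT replicate 1 and 0.02 without urt1 replicate 2. In abundance, less conserved families such as miR158 and miR403 had a median log2 fold of 0.22, with 55 of 77 names, from 74 different sequences, above 0. Conserved families, which are all other names, had a median of 0.04, a mean of -0.02 and a downward test, and their median was -0.02 with DESeq2 size factors and -0.05 with total reads. Both had a camera adjusted p of 0.0323, and an adjusted p of 0.995 with an estimated correlation. Since camera sets a list against all other names, both tests are the same comparison seen from either side. Without WT replicate 1 and without urt1 replicate 2 both calls ended and the tests turned, with medians for conserved families of 0.15 and 0.17. In these 3 lists 0 members passed, over all names or adjusted over the list alone.

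The reported nucleotidyl transferase substrates had a median log2 odds ratio for tailing of 0.14, with 16 of 24 names, from 14 different sequences, above 0 and a camera adjusted p of 0.547. Silencing pathway miRNAs and phased siRNA triggers had a median of -0.14, with 5 of 18 names, from 14 different sequences, above 0 and an adjusted p of 0.547. Neither list passed for uridylation or abundance by camera, and the lists by mature length and by first base passed in none of the tests by camera. By fry, which asks whether the members move one way on balance, miRNAs of 20 nt passed for abundance with an adjusted p of 0.00716, a median of 0.15 and 16 of 21 names, from 14 different sequences, above 0. This call depended on the scaling: adjusted over the 15 lists of the abundance fit, the fry p was 0.00239 with TMM, 0.672 with DESeq2 size factors (median 0.08) and 0.986 with total reads (median 0.12), a comparison chosen after the data were seen. It also ended when any 1 library was left out, with adjusted p values by fry of 0.903 without WT replicate 1, 0.974 without WT replicate 2 (median -0.01), 0.859 without urt1 replicate 1 and 0.979 without urt1 replicate 2. The median over all 185 names was 0.06 with TMM, 0.01 with DESeq2 size factors and 0.04 with total reads. In all, 5 of 45 list tests passed by camera with the preset correlation, with the single comparison of conserved and less conserved families in abundance counted once for each list. Of the members of any list 0 passed adjusted over the list alone.

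Among siRNAs siR-8 held most reads, at 866956 ± 97124 RPM of the siRNA table in WT and 901093 ± 18132 in urt1 (SD, n = 2 each). For siR-1 the values in WT and urt1 were 1568 ± 748 and 1022 ± 227, and for siR-2 680.1 ± 555 and 429 ± 153 (SD, n = 2 each). The edgeR test called 0 of 8, with 0 unadjusted p values under 0.05. By DESeq2 2 were called, siR-1 as lower with a log2 fold of -0.36 and siR-6 as higher with 0.56. Their standard errors were 0.12 and 0.17 by DESeq2, against 0.38 for both by edgeR. Both calls thus rest in part on a smaller estimated spread, which 2 libraries per group measure poorly. Without WT replicate 2, edgeR called siR-1 and siR-2 as lower, with log2 folds of -0.89 and -1.20. The median log2 fold of the 8 siRNAs was -0.33 with TMM, 0.01 with DESeq2 size factors and -0.18 with total reads, and relative to the TMM median siR-1 lay lower and siR-6 higher.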

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

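Counting genome-matching tails as untailed and the fry test under other scalings were chosen after the data were seen. The settings compared gave 1255 values. For single named miRNAs and siRNAs and for shares by tail base or length, 1148 of 1167 values kept their side of the threshold or stayed within the replicate spread. In 113 of these, all for single named miRNAs and siRNAs, the sign of an uncalled estimate changed. That was counted as kept since no direction was called. Sign changes of the shares by tail base or length were not counted. Each setting for miRNA tailing gave 0 calls by its own test. For miRNA uridylation the count was 0 in each setting except when 1 library was left out (0 to 1, with 1 without urt1 replicate 2, miR158a-3p at -0.65). For miRNA abundance it was 1 with no filter beyond 1 read and 0 to 6 when 1 library was left out (6 without urt1 replicate 1). For siRNA tailing it was 0 to 1 when 1 library was left out, with siR-8 at 0.15 without urt1 replicate 1, against the direction of its value over all libraries (-0.05), and at -0.25 without urt1 replicate 2. For siRNA abundance it was 2 with the DESeq2 Wald test and 0 to 2 when 1 library was left out (2 without WT replicate 2). The lists gave 5 calls with the preset correlation, 0 with an estimated correlation and 2 to 3 when 1 library was left out. The siRNA tailed share differed by -0.386 percentage points with an equal-weight mean, against 0.00726 over reads, where siR-8 takes most of the weight. Otherwise the cause was not tested. With 1 library left out, the lone library is assumed to vary like the other group.

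The replicate block gave 0 calls in each test of single miRNAs or siRNAs and 5 list calls by camera, and the fry call for miRNAs of 20 nt had an adjusted p of 0.0982. Deviations of same-numbered replicates correlated across miRNAs at r = 0.45 for abundance, 0.0675 for tailing and -0.0343 for uridylation, and with 2 pairs the numbers are not taken as pairing. For abundance, the edgeR test by replicate number in place of genotype gave 0 calls but 32 unadjusted p values under 0.05, against 2 by genotype. With the replicate block the genotype test gave 16. A difference tied to replicate number is thus not excluded for abundance. Within replicate numbers 1 and 2 the tailed miRNA share differed by -1.25 and 5.75 percentage points, the trimmed share by -0.840 and 2.77. Depth limits the rarer names: in simulations of the 132 names, 71.7% of 2-fold changes in the odds were called for miRNAs with at least 100 reads in every library, against 54.8% over all. Both rates hold for the simulated settings and may be too high for the data.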

Other observations

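All tests in this part were chosen after the values were seen. Longer tails went with trimmed ends in many miRNAs. Among 27 sequences with at least 100 full-length and 100 trimmed reads in every library, tails of 2 nt or more were more frequent on trimmed than on full-length ends in all 4 libraries for 14 and less frequent in all 4 for 5. The mean share over libraries was 32.8% on trimmed and 1.11% on full-length ends for miR158b, 21.8% and 0.738% for miR156d-5p, and 14.8% and 4.43% for miR850. The opposite held for miR161.2, with 4.70% on trimmed and 9.75% on full-length ends, and for miR5642a, with 0.0513% and 91.7%. Across the 132 tested names, which are not independent replicates, the tailed shares of any 2 libraries correlated at r = 0.93 to 0.95, within and across genotypes.

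Of A-tailed miRNA reads, at least 71.6% matched the genome over the whole read, at any place, in every library, as they would if A tails were mostly genome sequence. For U tails the share was at most 7.48%, for C tails at most 24.8% and for G tails at most 34.2%. This argues against genome sequence as the main source of these over all reads, though G tails still followed the next base. The U share rests largely on miR158a-3p, which gave 66.2% to 77.0% of U-tailed reads, with 0% of them matching. Among the other miRNAs the matching share of U tails is therefore higher. The median share of 1-nt A tails was 0.991% in the 43 names whose next genome base is A and 0.00354% in 81 others, and that of 1-nt G tails 6% in 7 names whose next base is G and 0% in 117 others (each a one-sided permutation p = 1.0e-05, the smallest the permutations can give, adjusted p = 2.0e-05 over 4 bases). For U tails the medians were 1.74% and 1.53% (permutation p = 0.398) and for C tails 0.357% and 0.383% (permutation p = 0.527), each with an adjusted p of 0.527. Names were permuted as separate units, although names with the same sequence divide their reads and are not independent. The p values may thus be too small. Copies can also differ in next base, which blurs the U and C comparisons. For the miR165a-3p sequence it is C at MIR165a and T at MIR165b. An earlier ratio pooled over the 4 bases, 56.2, mixed bases of different levels and was replaced by the shares per base after its value was seen, and no biological explanation was tested.

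Ends of miR158a-3p trimmed by 1 nt were tailed on 38.0% to 81.1% of reads, with both extremes in different genotypes and the other libraries between them, while full-length ends stayed between 20.7% and 23.3%. Size selection of the libraries is argued against as the whole cause, since among reads of 20 nt the share of trimmed and tailed reads still ranged from 6.89% to 17.5%, a ratio of 2.54. Mislabelled libraries cannot be told apart from other differences among the samples: the labelled split called 0 miRNAs for uridylation and another split of the 4 libraries into pairs called 8, but that split joins the same libraries as the shares that prompted the test, so it is not independent evidence. It called 3 for tailing and 0 for abundance, the 3 possible splits are too few for a share under 0.05, and the URT1 transcript, which would check the labels, was not analysed here. With the labels as given, genotype is argued against as the whole cause, since the replicates lay farther apart than the genotype means, at 81.1% and 54.0% in WT and 38.0% and 76.3% in urt1, while a smaller part of genotype stays open, as does a difference between the seedlings, which was untested.

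The siRNAs siR-4, siR-6 and siR-8 held 93.8% to 97.9% of siRNA reads, and each matches places past annotated ribosomal RNA genes on chromosomes 2 and 3. On each chromosome the distance past the gene was 416 bp for siR-4, 3475 bp for siR-6 and 3556 bp for siR-8. On chromosome 3 these places follow AT3G41979, with siR-8 at 14203472 to 14203491. There they lie in an exon of AT3G06365, an uncharacterized RNA gene of the same strand. These positions alone do not show whether the siRNAs are parts of ribosomal RNA, since no annotated ribosomal RNA gene covers them. Both siR-6 and siR-8 also match a place on chromosome 3 before AT3G41979, at 14192982 and 14193063. No annotated ribosomal RNA gene of the same strand lies before that place. Fragments of ribosomal RNA, a candidate explanation, cannot be told apart from Dicer products by length: at most 38.1% of their untailed reads in any library were 21, 22 or 24 nt long, but siR-8 is listed at 20 nt and siR-4 at 19 nt, outside these classes, so that a low share was largely set in advance. For siR-6, listed at 22 nt, the share was 6.55% to 17.6%, and its commonest length was 27 nt in every library. Low shares were not limited to these loci, with 12.3% to 19.1% for siR-5, listed at 21 nt, and 33.7% to 56.6% for siR-1, listed at 22 nt. Nor were they general, with 90.4% to 97.5% for siR-2, listed at 24 nt, and 79.8% to 85.7% for siR-3, listed at 21 nt. No biological explanation was tested.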
